A study of Caulobacter vibrioides with 6 samples.

How the data were processed

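OpaA ChIP-seq was carried out on Caulobacter crescentus NA1000 with a polyclonal rabbit antibody. The 6 samples were 2 untreated wild-type replicates, 1 wild-type sample for each of rifampicin, novobiocin and chloramphenicol, and 1 suppressor strain without opaA, which was not analysed here. Samples were grouped by their titles and genotypes, per the labels. Treatment lasted 10 min, and cells were cross-linked with formaldehyde before lysis and sonication, per the labels' protocols. CASAVA 1.8.2, Bowtie 0.12.9, SAMtools 0.1.18 and MACS2 2.1.0.20151222.0 were used, per the submitters' processing notes. The genome build, the control library of the peak calling and the mapping settings are not given in the sources used here.

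The deposited files used are 5 peak lists, 1 for each wild-type sample, called by MACS2 at a q-value of 0.05, per the file headers. Each row holds the start, end, length and summit of a peak, the closest coding sequence and the local sequence around the summit. The pileup at the summit is a signal in reads, the number of fragments stacked there, per the file headers. Significance is given as -log10 of the p-value and of the q-value, per the file headers. Enrichment is a fold, the ratio of the pileup to the local background, per the file headers. The GC content around the summit is a percent, per the file headers. Each list was called on 1 dataset, not on pooled samples, per the file headers, so the replicates could be compared as lists. Across the 5 lists the peak numbering leaves out 10 peaks, which were not used here. No column of per-sample values was left out.

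The deposited values were checked against each other. The fold and the pileup imply the local background, and the Poisson probability of the pileup over it should return the deposited p-value. This held within 1% for 100% of the peaks checked in 4 lists, and for 0.468% in untreated replicate 2. There the -log10 p and q values divided by 1.8 and the folds divided by 1.2 returned the Poisson value within 1% for 100% of 1281 peaks. All positions and ranks of that list are free of such factors, and any threshold on its values was also applied to the values divided back. The deposited GC percent of untreated replicate 2 covered 75 bp on either side of the summit and that of untreated replicate 1 covered 50 bp. In the treated lists it was within 1 percentage point of the value over 50 bp, and why it differed was not established. A+T content was therefore recomputed from the deposited sequences for all lists, over the summit base and 50 bp on either side. In 1 chloramphenicol peak the sequence was short, and its A+T content was left out.

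A summit inside a region counted as shared. Untreated regions were the replicate 1 regions that held at least 1 replicate 2 summit, and an untreated region was retained when it held at least 1 treated summit. Chance was measured by an exact rotation test: the summits were shifted around the circular chromosome by each of its 4042902 positions (the largest peak end was taken as the length), and the two-sided p is the share of shifts with a value as extreme, multiplied by 2. The test keeps the spacing of the peaks and speaks of positions on the chromosome, not of replicates. The 3 treatments share the same untreated regions, so their results are not independent. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which cover counting error over peaks only. Retention was compared between quartiles of the authors' fold in replicate 1 by exact rotation of the retained labels along the chromosome. Treated summits counted as outside when no region of either untreated replicate held them. A+T content of treated summits inside and outside these regions, and of retained and lost untreated regions, was compared by the same rotation of labels. The central 51 bp and the outer parts of each sequence, 50 bp on each side, were compared by a sign-flip permutation test with 100000 draws, which takes peaks as independent. P-values were adjusted by the Benjamini-Hochberg method within each family of results, with a threshold of 0.05.

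Gene names come from the closest coding sequence in the deposited lists. The order of 3886 protein-coding genes and 665 symbols came from the RefSeq gene table of assembly ASM2200v1, used only for names and gene order. Of the peaks 1177 of 1188 and 1279 of 1282 in the untreated lists matched a gene of that table, as did 219 of 221 after rifampicin, 1360 of 1367 after novobiocin and 1019 of 1046 after chloramphenicol. Groups of genes were tested by rotating the marks of named genes along the gene order. No genome sequence and no strands or product texts were used, so the planned analyses of position relative to genes and along runs of genes on 1 strand were not run, nor were the groups for rRNA, tRNA, TonB-dependent receptors, mobile elements and hypothetical proteins. The A+T content was planned as a rotation test over a genome and was replaced by the comparison of central and outer parts. Translation factor symbols had no match, and groups with fewer than 3 matched genes were not tested.

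The named regions followed a rule fixed before the data were examined: the 10 untreated regions with the highest replicate 1 fold and, for each treatment, the 5 retained regions with the highest treated fold, the 8 regions without a treated summit with the highest replicate 1 fold, and the 8 treated summits outside the regions of either untreated replicate with the highest treated fold. The rule named a peak by the gene that holds the summit, which was replaced by the closest coding sequence. Genes of the topoisomerase, cell cycle and RNA polymerase groups were named where a peak lay closest to them. The summits nearest to the untreated parB summit were looked up after its values were seen.

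Alternatives fixed before the data were examined were region overlaps of at least 1 bp or of 50% of the shorter region, stricter thresholds (-log10 q of at least 10, fold of at least 2), equal numbers of top peaks (221 per list), each untreated replicate left out, and a narrower A+T window of 25 bp on either side. Thresholds with replicate 2 values divided back, an A+T window of 75 bp on either side and equal windows around the untreated summits were added after seeing the data. The rotation test was tested on rotated and simulated lists, and 0 of 20 shifts differed from a direct count. Of 100 random rotations of the 221 rifampicin summits, 5 gave a p under 0.05 against untreated replicate 1. A share near that threshold is fixed by the test itself, so it does not measure false positives on independent lists. With 20% of summits planted in the regions of replicate 1, 20 of 20 lists were recovered. For the gene groups, 1 of 40 simulated groups was called with no change and 40 of 40 with marks raised 3 times. The simulated groups were larger than most tested groups, held more marks than the rifampicin list gave, and were called at an unadjusted p. Power for the small groups and for rifampicin was therefore not measured. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.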

Results

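OpaA is a nucleoid-associated protein of Caulobacter crescentus (also named Caulobacter vibrioides), an alphaproteobacterium that divides asymmetrically and carries a single circular chromosome. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with a rabbit antibody against OpaA located the protein on the chromosome of the wild-type strain NA1000, grown to mid-log phase in rich medium. Peak lists were analysed for 2 replicates of untreated cells and for 1 library each of cells treated for 10 min with rifampicin (30 µg/ml), which blocks RNA polymerase, novobiocin (100 µg/ml), which inhibits DNA gyrase, and chloramphenicol (1 µg/ml), which blocks translation. The ChIP-seq sample from a viable suppressor strain without opaA was not analysed here, so the specificity of the antibody at the named peaks was not checked. The series was designed to ask where OpaA lies on the chromosome of growing cells and whether its peaks are redistributed by these drugs.

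The untreated lists held 1188 and 1282 peaks, the rifampicin list 221, the novobiocin list 1367 and the chloramphenicol list 1046. Peak regions covered 21.4% and 10.6% of the chromosome in untreated replicates 1 and 2, 1.44% after rifampicin, 8.92% after novobiocin and 11.1% after chloramphenicol. The median peak was 302.5 and 204 bp long in the untreated replicates, and 163, 183 and 258 bp long after rifampicin, novobiocin and chloramphenicol. Total read numbers were unknown, so the lowest background pileup that the peak values imply was taken as an indirect measure of depth. It was 501 reads in untreated replicate 1, 528 in replicate 2 (from folds divided by 1.2), 74.0 with rifampicin, 46.3 with novobiocin and 158 with chloramphenicol. This background was lower in the treated lists than in the untreated ones. It may also depend on the control library and the settings, which are not given, so library depth itself was not established. Which of the peaks missing from a treated list could have been detected at its depth was not tested. No test between conditions was run, as each treatment has 1 library, and the 2 untreated lists give the only measure of spread. Nothing in the labels says that these came from separate cultures, so their spread may be technical. Fold enrichments are those of the authors' peak caller. A common fold threshold was applied to all lists as an alternative, but folds of different lists were not tested against each other. The folds of untreated replicate 2 are printed as deposited, which is 1.2 times what its own pileups imply. All positions are coordinates on the chromosome as deposited, with a genome build that is not given in the sources used here. Each peak is named by the closest coding sequence in the deposited lists, and whether its summit lay inside that sequence was not analysed here.

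**Figure D1:**
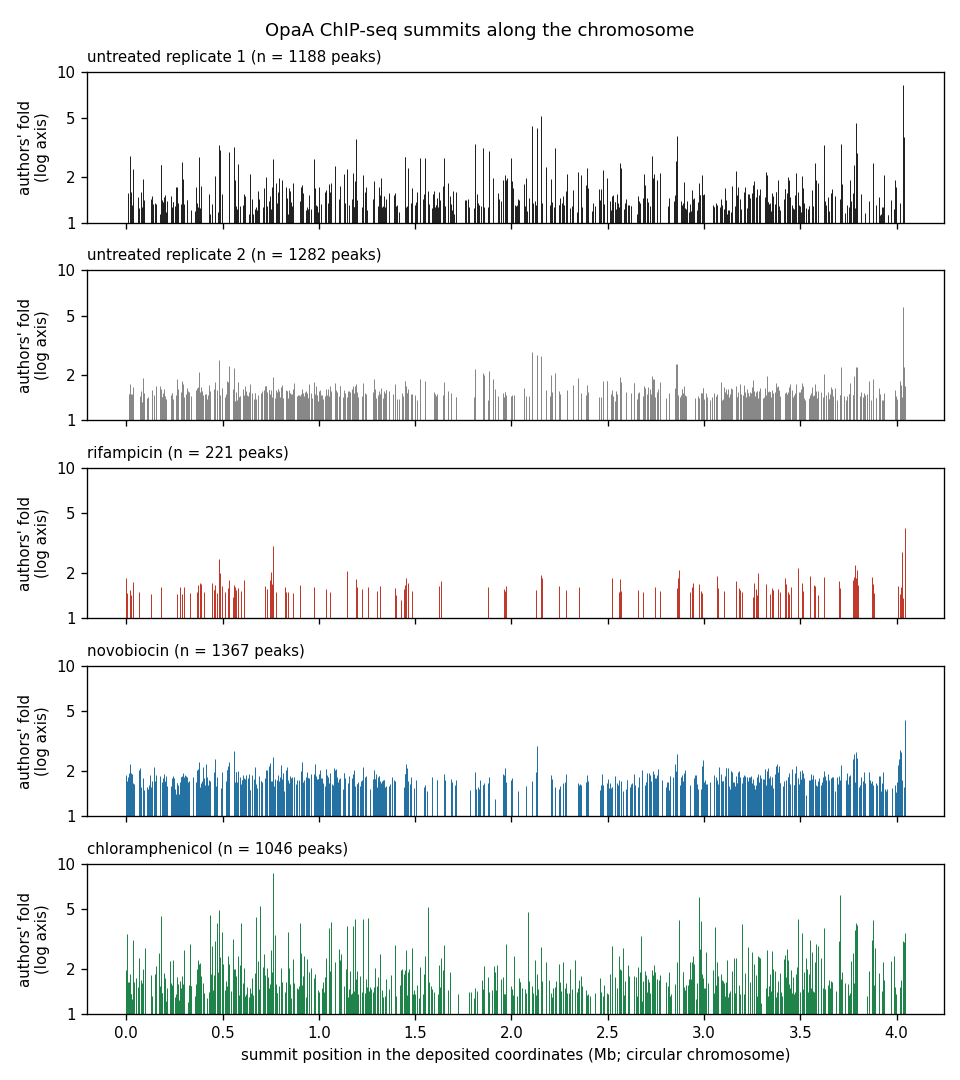
Each vertical line is the summit of 1 peak, drawn at its position (Mb) and up to the authors' fold enrichment (log axis), for the 5 peak lists. The highest line in both untreated lists stands at the parB locus near the right end (folds of 8.31 and 5.70), and in the chloramphenicol list at cspB (fold of 8.74).

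In untreated cells the strongest OpaA peak of both replicates lay at parB, the gene of the partition protein that binds the centromere-like parS sites. In replicate 1 this region ran from 4017280 to 4031932 with its summit at 4030483 (fold of 8.31, rank 1 of 1188), and in replicate 2 from 4027240 to 4031972 with its summit at 4030513 (fold of 5.70, rank 1 of 1282). A cluster of 3 strong regions lay on the far side of the chromosome from the origin, next to CCNA_01962 (2106027 to 2107283, fold of 4.41 in replicate 1), CCNA_01985 (2128658 to 2134519, 4.25) and CCNA_02005 (2152312 to 2155778, 5.10). The replicate 2 regions over these 3 summits ranked 2, 3 and 4. The other regions among the 10 with the highest replicate 1 fold were CCNA_03633 (3787774 to 3789205, 4.62), CCNA_02704 (2859168 to 2862274, 3.77), CCNA_03877 (4038020 to 4042884, 3.73), CCNA_01085 (1189198 to 1191890, 3.60), CCNA_01682 (1808124 to 1811753, 3.36) and CCNA_03556 (3711656 to 3713598, 3.32).

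The replicates shared more positions than rotations of the chromosome gave, but their lists differed in many peaks. Of the replicate 2 summits, 816 of 1282 (63.7%, 95% exact binomial interval 60.9 to 66.3) lay inside replicate 1 regions, against a mean of 21.4% over all rotations of the summits around the chromosome (two-sided exact rotation test, Benjamini-Hochberg adjusted p = 3.96e-06 over the 8 overlap results). In the other direction 286 of 1188 replicate 1 summits (24.1%, 21.7 to 26.6) lay inside the shorter replicate 2 regions, against 10.6% over the rotations (exact adjusted p = 1.19e-05). This share was 40.6% when any overlap of at least 1 bp counted, 36.8% with an overlap of 50% of the shorter region, and 6.58% of 76 peaks with a fold of at least 2 and replicate 2 divided back, where all 5 replicate 2 summits (100%) lay in replicate 1 regions; each passed (largest exact adjusted p = 0.0014). The 424 replicate 1 regions that held at least 1 replicate 2 summit, 621.6 kb in all, served as the untreated reference. Origin-proximal shares, the share of summits at most 25% of the chromosome length away from the origin on either side, were 52.6% (49.7 to 55.5) and 66.5% (63.8 to 69.0) in replicates 1 and 2. They were 71.5% (65.1 to 77.3) with rifampicin, 68.8% (66.3 to 71.3) with novobiocin and 56.5% (53.4 to 59.5) with chloramphenicol. None of these 5 shares passed the rotation test against its mean of 50% (adjusted p between 0.262 and 0.298). Rotation keeps any gradient along the chromosome, so it tests only whether the dense part is centred on the origin. For the overlaps, most rotations move the dense parts of the lists apart, so a shared gradient can also raise an overlap above the rotations. In 10 equal parts, those next to the origin held 161 and 128 replicate 2 summits and those opposite 44 and 44. The counts were 119 and 93 against 87 and 104 in replicate 1, and 24 and 32 against 8 and 12 with rifampicin. They were 174 and 177 against 45 and 46 with novobiocin, and 134 and 73 against 70 and 77 with chloramphenicol.

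After rifampicin, OpaA peaks were few, and the parB summit was no longer the highest. The list was led by hemE, the uroporphyrinogen decarboxylase gene beside the origin of replication (4039334 to 4042902, summit 4042436, fold of 3.97). This summit lay inside the untreated replicate 1 region named CCNA_03877 (fold of 3.73, rank 7), which had its own summit at 4039917. The replicate 2 region over the hemE summit had a fold of 1.49 (rank 578 of 1282), and the one over the CCNA_03877 summit a fold of 2.27 (rank 11). The hemE peak was followed by cspB, a cold shock protein gene (761021 to 761887, summit 761385, 3.01), and by CCNA_03865 (4021590 to 4029272, summit 4026192, 2.77), which lies inside the untreated parB region but away from its summit. The rifampicin summit nearest to the untreated parB summit, 122 bp from it, had a fold of 1.37 and ranked 218 of 221. The next retained peaks were CCNA_03922 (483822 to 484515, 2.48) and CCNA_03624 (3781230 to 3781646, 2.25).

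Rifampicin summits lay in 64 of the 424 untreated regions (15.1%, 95% exact binomial interval 11.8 to 18.9), more than the 6.02% over the rotations (exact rotation test, adjusted p = 4.35e-05). The other 360 regions held no rifampicin summit, and 0 of them were overlapped by a rifampicin region. The 8 with the highest untreated fold among them were CCNA_01962, CCNA_01682, CCNA_03556, CCNA_02074, CCNA_01726, CCNA_01755, CCNA_02578 and rplQ, the gene of ribosomal protein L17, with replicate 1 folds from 4.41 down to 2.74. Of the 10 strongest untreated regions 7 held a rifampicin summit, often away from the untreated one. A rifampicin region covered the untreated summit itself only at parB (a peak of rank 218), CCNA_02005, CCNA_03633 and CCNA_03877. The retained share was 3.51% with all replicate 2 regions as the reference and 8.50% with all replicate 1 regions. It was 3.56% with a deposited -log10 q of at least 10 (5.19% with replicate 2 divided back) and 35% with the top 221 peaks of each list. Each share was above the rotations (largest exact adjusted p = 0.00333). Retention went with untreated strength: 44 of 106 regions (41.5%) in the top quartile of replicate 1 fold held a rifampicin summit, against 2 of 106 (1.89%) in the bottom quartile. This difference of 39.6 points gave an exact p = 0.00472, before and after adjustment over the 3 treatments, the smallest that 424 rotations of the labels can give. Regions of the top quartile were longer (median 2684 against 264.5 bp), and rotations alone gave 12.01% and 1.85% in those quartiles. With windows of equal width around the replicate 1 summits the difference was 20.8 points (exact adjusted p = 0.00708), and with the regions and folds of replicate 2 it was 9.35 points (exact adjusted p = 0.00156).

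Rifampicin summits outside the regions of either untreated replicate numbered 63 of 221 (28.5%, 22.7 to 34.9), fewer than the 76.0% over the rotations (exact adjusted p = 3.0e-05). Without replicate 1 the share was 74.2% against 89.4% (exact adjusted p = 0.00287), and with the top 221 peaks 45.7% against 86.9% (exact adjusted p = 8.6e-05). The 8 with the highest fold were CCNA_02708 (summit 2868181, fold of 2.11), ctrA, the gene of the master cell cycle response regulator (3279786 to 3280137, summit 3279872, 2.01), CCNA_02910 (3069524, 1.92), CCNA_03706 (3874336, 1.89), CCNA_00001 (224, 1.86), CCNA_03542 (3699415, 1.78), the flagellin gene fljL (1635169, 1.77) and CCNA_03129 (3278798, 1.77). Of these 8 summits, 7 lay inside a chloramphenicol region and CCNA_00001 did not.

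After novobiocin the highest peak was again at hemE beside the origin (4041237 to 4042849, summit 4042562, fold of 4.41), inside the same untreated region, CCNA_03877. It lay away from the summit of that region, and the untreated replicate 2 region over it had a fold of 1.58 (rank 255 of 1282). The next novobiocin peaks were CCNA_01985 of the cluster opposite the origin (2130396 to 2132173, summit 2131168, 2.96), CCNA_03853 (4017260 to 4019009, summit 4018556, 2.76), at the edge of the untreated parB region, CCNA_00538 (556528 to 557999, 2.74) and CCNA_03634 (3788170 to 3788791, 2.69). At parB itself no strong peak was listed: the novobiocin summit nearest to the untreated parB summit lay 597 bp from it and had a fold of 1.44, rank 1336 of 1367. The neighbouring regions of the opposite cluster, CCNA_02005 and CCNA_01962, held no novobiocin summit.

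The deposited novobiocin list was no shorter than the untreated ones, but with a -log10 q of at least 10 it kept 46 peaks, against 567 and 687 in the untreated lists (296 for replicate 2 with its values divided back). Novobiocin summits lay in 212 of the 424 untreated regions (50%, 45.1 to 54.9), against 26.6% over the rotations (exact adjusted p = 1.35e-05). With all replicate 1 regions as the reference the share was 22.7%, and with all replicate 2 regions 38.1%. With a deposited -log10 q of at least 10 it was 9.09% (13.0% with replicate 2 divided back). Each share was above the rotations (largest exact adjusted p = 2.66e-04). Of the 10 strongest untreated regions 7 held a novobiocin summit. A novobiocin region covered the untreated summit itself only at CCNA_03633, CCNA_01985 and CCNA_02704. Besides CCNA_02005 and CCNA_01962, the strongest untreated regions without a novobiocin summit were CCNA_01085, CCNA_00467, CCNA_03922, CCNA_02578, rplQ and CCNA_01862, with replicate 1 folds from 3.60 down to 2.71. Of the 212 regions without a novobiocin summit 41 were overlapped by a novobiocin region. Retention was 65.1% in the top and 23.6% in the bottom quartile of untreated fold, a difference of 41.5 points (exact p = 0.00472, the smallest that 424 rotations of the labels can give). Rotations gave 45.7% and 10.7% in the same quartiles, whose regions differed in length as above. With windows of equal width around the untreated summits the difference turned to -8.49 points and did not pass (exact adjusted p = 0.193), and with any overlap of at least 1 bp it was 16.5 points (exact adjusted p = 0.0249). With the regions and folds of replicate 2, whose lengths were not equalised, it was 33.3 points (exact adjusted p = 0.00156). Outside the regions of either untreated replicate lay 634 of 1367 novobiocin summits (46.4%, 43.7 to 49.1; rotations 76.0%, exact adjusted p = 1.19e-05). Without replicate 1 the share was 56.5% (rotations 89.4%), without replicate 2 61.4% (rotations 78.6%) and with a fold of at least 2 58.5% (rotations 93.5%). With a deposited -log10 q of at least 10 it was 13.0% (rotations 80.5%), and 17.4% with replicate 2 divided back (rotations 81.6%). Each share was below the rotations (largest exact adjusted p = 4.52e-04). Of the 8 strongest of these summits, 4 lay in a stretch near the origin, at moeB, a gene of molybdenum cofactor synthesis (summit 4009503, fold of 2.20), CCNA_03844 (4010560, 2.12), CCNA_03845 (4012126, 2.41) and CCNA_03849 (4015467, 2.22). The others were CCNA_02919 (3077673, 2.13), CCNA_00381 (397977, 2.12), CCNA_03174 (3333903, 2.11) and CCNA_00070 (72860, 2.10).

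After chloramphenicol the strongest OpaA peak lay at cspB (760458 to 763526, summit 761400, fold of 8.74), inside an untreated replicate 1 region that ranked 30 with a fold of 2.65 and had its own summit at 762453, next to CCNA_00703. The parB peak was kept at the same place, with its summit 9 bp from the untreated one, but at rank 45 of 1046 (4020916 to 4031252, fold of 3.07). The next retained peaks by fold were CCNA_03549 (3707875 to 3708755, 6.25), CCNA_03709 (3875837 to 3877188, 4.26), CCNA_00982 (1061075 to 1061911, 4.13) and CCNA_01051 (1147679 to 1148662, 3.89).

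Chloramphenicol summits lay in 170 of the 424 untreated regions (40.1%, 35.4 to 44.9), against 24.6% over the rotations (exact adjusted p = 3.0e-05), and in 8 of the 10 strongest. With all replicate 1 regions as the reference the share was 29.7% (rotations 13.7%, exact adjusted p = 1.68e-05), and with all replicate 2 regions it was 9.59%, close to the 7.83% over the rotations (exact adjusted p = 0.0322). Retention was 9.43% in the bottom and 80.2% in the top quartile of untreated fold, a difference of 70.8 points (exact p = 0.00472, the smallest that 424 rotations of the labels can give). Rotations gave 8.62% and 45.3% in those quartiles, and windows of equal width gave a difference of 44.3 points (exact adjusted p = 0.00708); with the regions and folds of replicate 2 it was 20.9 points (exact adjusted p = 0.00156). The strongest untreated regions without a chloramphenicol summit were CCNA_03633, CCNA_01085, CCNA_00467, CCNA_03922, CCNA_03637, CCNA_02578, rplQ and CCNA_02699. In 6 of these 8, all but CCNA_02578 and CCNA_02699, the untreated summit was inside a chloramphenicol region whose own summit lay elsewhere. Among all 254 regions without a chloramphenicol summit, 25 were overlapped by a chloramphenicol region. Outside the regions of either untreated replicate lay 466 of 1046 chloramphenicol summits (44.6%, 41.5 to 47.6; rotations 76.0%, exact adjusted p = 1.19e-05). Without replicate 1 this share was 83.8% (rotations 89.4%, exact adjusted p = 0.00377), with a fold of at least 2 it was 79.4% (rotations 93.5%) and with the top 221 peaks 69.2% (rotations 86.9%). The 8 strongest of these were CCNA_02816 (2973684 to 2974380, fold of 6.02), CCNA_00639 (691395 to 692182, 5.26), CCNA_01457 (1566717 to 1568109, 5.16), CCNA_00466 (476535 to 486490, 4.98), CCNA_01944 (2086158 to 2086803, 4.77), CCNA_00425 (435495 to 436277, 4.57), CCNA_00169 (179913 to 181506, 4.49) and the chemotaxis regulator gene cheY (673363 to 674437, 4.48). No region of another list covered any of these 8 summits, and their A+T contents lay between 55.4% and 67.3%. Only the summits lay outside, as some of these chloramphenicol regions overlapped untreated ones. The CCNA_00466 region held the replicate 1 summits of CCNA_00467 and CCNA_03922 (folds of 3.26 and 3.05). The regions of CCNA_00169, CCNA_01457 and cheY also held a replicate 1 summit.

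**Figure D2:**
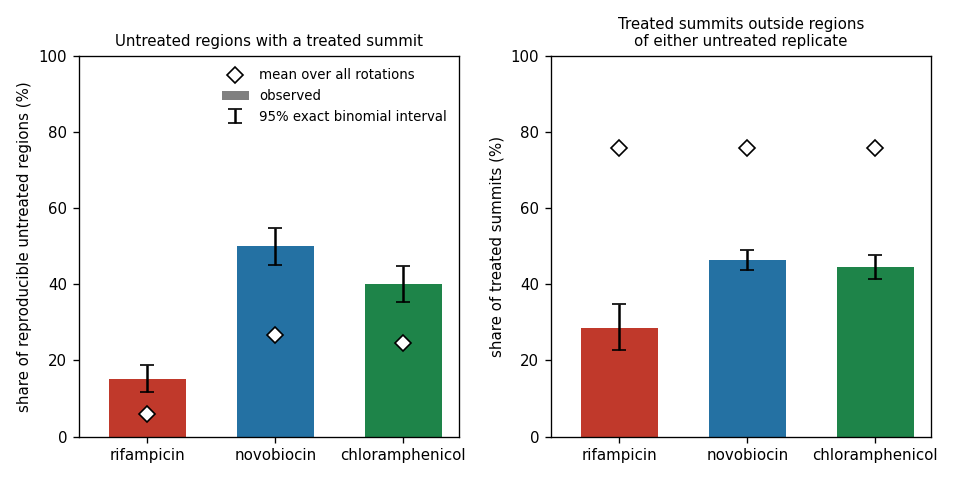
Left, bars give the share (%) of the 424 untreated regions that held at least 1 summit of the treated list (15.1% for rifampicin, 50% for novobiocin and 40.1% for chloramphenicol). Right, bars give the share (%) of treated summits outside the regions of either untreated replicate; error bars are 95% exact binomial intervals, and diamonds are the means over all rotations, which lie below the bars on the left and above them on the right.

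The base composition of the sites differed between the lists. Mean A+T content within 50 bp of the summit was 35.5% ± 4.86 (SD over 1188 peaks) in untreated replicate 1 and 30.7% ± 3.83 (1282 peaks) in replicate 2, a difference of 4.82 points between replicates. It was 42.2% ± 7.09 after chloramphenicol (1045 peaks with a full sequence), 40.5% ± 6.17 after rifampicin (221 peaks) and 28.5% ± 3.42 after novobiocin (1367 peaks). The chloramphenicol mean was 6.64 points above untreated replicate 1, more than the replicates differed. The rifampicin mean was 4.92 points above it, about as much as the replicates differed, and the novobiocin mean was 2.22 points below replicate 2, less than they differed. Summits with an A+T content of at least 50% numbered 150 after chloramphenicol and 15 after rifampicin, against 4 and 0 in the untreated lists and 0 after novobiocin.

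Chloramphenicol summits were also richer in A and T than the sequence around them. The central 51 bp exceeded the outer parts of the same sequence by 2.83 points (sign-flip permutation test over peaks, adjusted p = 5.0e-05, from the smallest p the permutations can give). In untreated replicate 2 and after novobiocin the central part was poorer in A and T, by differences of -0.608 and -0.777 points (permutation adjusted p = 0.0011 and 2.0e-04). The differences of 0.357 points in untreated replicate 1 and 0.740 points after rifampicin did not pass (permutation adjusted p = 0.138 and 0.217). Treated summits outside the regions of either untreated replicate were richer in A and T than those inside after chloramphenicol (45.2% against 39.7%, label rotation test, exact adjusted p = 0.0057) and after rifampicin (42.2% against 39.8%, exact adjusted p = 0.0181). After novobiocin they were poorer (28.2% against 28.8%, exact adjusted p = 0.0088). Untreated regions that held a summit of the treated list had a higher A+T content than those that did not for rifampicin (37.1% against 33.9%) and chloramphenicol (35.9% against 33.4%, both with an exact adjusted p = 0.00708), but not for novobiocin (34.4% in both, exact adjusted p = 0.943).

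**Figure D3:**
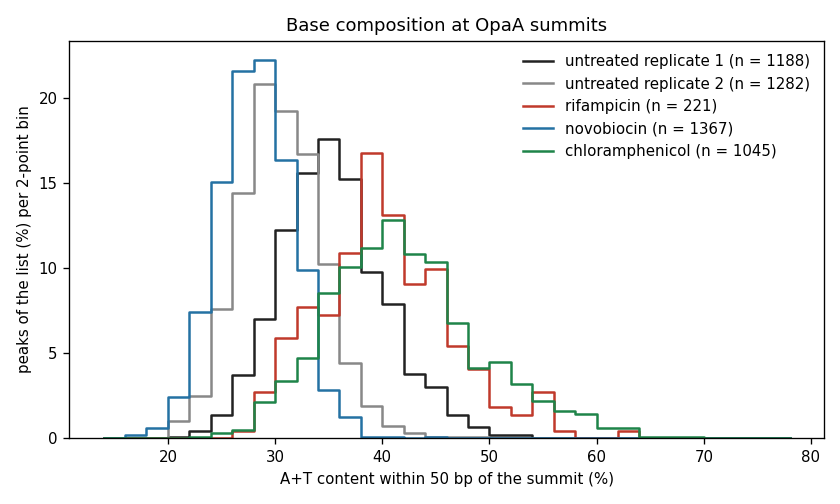
Lines give, for each of the 5 lists, the share of peaks (%) in bins of A+T content (%) within 50 bp of the summit. The chloramphenicol (mean 42.2%) and rifampicin (40.5%) lists lie to the right of the untreated lists (35.5% and 30.7%), and the novobiocin list (28.5%) to the left.

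No gene group fixed before the data were examined passed a test among the genes named by the peaks, and power for small groups was not measured. Of 40 tests (8 groups in 5 lists, exact rotation of the peak marks along the gene order), 0 passed after adjustment and 0 had an unadjusted p under 0.05; the smallest p was 0.0787 (adjusted p = 0.935), for 0 of 26 ribosomal protein genes after novobiocin. Of 19 cell cycle regulators, the untreated lists named dnaA, the replication initiator gene (fold of 1.20 in replicate 1), and divL (1.49 in replicate 2). The rifampicin list named ctrA (2.01) and dnaA (1.47), and the chloramphenicol list dnaA (3.41), ctrA (2.43), podJ (1.503), divK (1.37) and the DNA methyltransferase gene ccrM (1.31). The novobiocin list named divL (1.84), divJ (1.71), podJ (1.69) and cpdR (1.56). Of 7 genes of RNA polymerase subunits and sigma factors, rpoD, rpoH and sigF were named in untreated replicate 1, rpoA and rpoN after novobiocin, and rpoD and rpoN after chloramphenicol, with none in the other lists. Of 11 genes for replication, segregation and nucleoid proteins, parB was named in both untreated lists and after chloramphenicol, ihfB after rifampicin and chloramphenicol, and smc and mipZ after novobiocin. The untreated lists also named mipZ in replicate 1 and smc in replicate 2.

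None of the 14 NADH-quinone oxidoreductase genes was named in any of the 5 lists. Flagellar and chemotaxis genes named numbered 10 and 8 of 60 in the untreated lists, 2 after rifampicin (fljM and fljL), 9 after novobiocin and 15 after chloramphenicol. Ribosomal protein genes numbered 2 and 4 of 26 in the untreated lists, and 2, 0 and 5 after rifampicin, novobiocin and chloramphenicol. Chaperone and protease genes numbered 4 and 1 of 9 in the untreated lists, 0, 2 and 4 in the treated ones, with clpB in 4 of the 5 lists. Of 10 division and envelope genes, ftsZ was named in both untreated lists and ftsA in replicate 1, and 0 in each treated list. The gyrase subunit gene gyrB, the only topoisomerase gene that could be matched, was not named in any list, and of 2 ATP synthase genes atpA was named after chloramphenicol; these groups were too small to test.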

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

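Tests with values of untreated replicate 2 divided back, the A+T window of 75 bp on either side and the equal windows were chosen after seeing the data; the other alternatives were fixed before. Of 136 alternative values, 108 kept their direction and their side of the threshold or moved by less than the spread, 3 no longer passed, 1 changed direction and 24 moved. The overlap results passed in the same direction under every alternative run, except the retained shares under 1: with a fold of at least 2 and replicate 2 divided back, only 5 untreated regions were left, of which 20% held a rifampicin, 40% a novobiocin and 40% a chloramphenicol summit (exact adjusted p = 0.161, 0.155 and 0.421). Equal windows around the untreated summits turned the novobiocin difference between fold quartiles to -8.49 points (exact adjusted p = 0.193), where regions no longer differed in length. Leaving out untreated replicates gave retained shares of 3.51% to 8.50% for rifampicin, 22.7% to 38.1% for novobiocin and 9.59% to 29.7% for chloramphenicol, over other reference regions. Origin-proximal shares and gene groups did not pass under any alternative run for each.

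Peak numbers and covered lengths depended on the thresholds. With a -log10 q of at least 10 the numbers were 567 and 687 in the untreated lists (296 for replicate 2 divided back), 23 for rifampicin, 46 for novobiocin and 430 for chloramphenicol, and the regions covered 0.488% of the chromosome for rifampicin, 1.05% for novobiocin and 5.32% for replicate 2 divided back. With a fold of at least 2 the numbers were 76 and 24 (5 divided back), 12, 106 and 170, and the covered shares 6.43%, 1.22% (0.312% divided back), 0.398%, 1.74% and 4.57%. Mean A+T content moved to 46.5% for chloramphenicol and 43.9% for rifampicin with a -log10 q of at least 10, and to 49.6% for chloramphenicol with equal numbers of top peaks. These thresholds remove peaks by construction, and the part that depth plays in the numbers was not tested. No paired analysis was possible because the treated groups have 1 library each and share only 1 replicate number with the untreated group. The A+T window of 100 bp on either side, the extension of genes and all alternatives for position relative to genes and along directons were not run.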

Other observations

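The overlaps between treated lists and the tests of the number of peaks, of depth, of the scaling and of the multiplied values were chosen after the results were seen. Most rifampicin sites were also chloramphenicol sites. Of 221 rifampicin summits, 203 (91.9%, 95% exact binomial interval 87.4 to 95.1) lay inside chloramphenicol regions, against 11.1% over the rotations (exact rotation test, adjusted p = 3.4e-05 over 20 ordered pairs of lists), and with the top 221 peaks of each list the share was 60.6% against 5.32%. The longer chloramphenicol list was mostly not shared: 111 of its 1046 summits (10.6%, rotations 1.44%) lay in rifampicin regions, and 27.1% with the top 221 peaks. The cold shock gene cspB ranked 2 and 1 in these lists, with folds of 3.01 and 8.74. For novobiocin, 43.5% of its summits lay in regions of untreated replicate 2 (rotations 10.6%, exact adjusted p = 7.4e-06), but 9.44% in chloramphenicol regions (rotations 11.1%, exact adjusted p = 0.283), and chloramphenicol summits lay in novobiocin regions less often than the rotations gave (5.74% against 8.92%, exact adjusted p = 9.28e-04). These relations depended on the peaks used. With the top 221 peaks of each list the last share was 1.81% against 2.75% and did not pass (exact adjusted p = 0.555), while novobiocin summits lay in chloramphenicol regions more often than the rotations gave (13.6% against 5.32%, exact adjusted p = 0.00566). Novobiocin summits then also lay more often in rifampicin regions (5.88% against 1.44%, exact adjusted p = 0.00614), and rifampicin summits in novobiocin regions (8.60% against 2.75%, exact adjusted p = 0.00914), which did not pass with all peaks (exact adjusted p = 0.651 and 0.312). Both lists were dense near the origin (origin-proximal shares of 68.8% and 71.5%). Such a shared gradient can raise an overlap above the rotations without shared sites, and whether it did was not tested.

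Some untreated regions held summits of every treated list, though not always at the same place. Of the 424 untreated regions, 46 (10.8%) held a summit of all 3 treated lists, 100 held novobiocin summits alone, 48 chloramphenicol summits alone and 4 rifampicin summits alone, and 148 held none. The regions in all 3 included the long parB region, where the treated summits lay at different places, CCNA_01985 opposite the origin, CCNA_02704 (2859168 to 2862274), CCNA_03877 next to the origin, CCNA_03459 (3618994 to 3624549) and moaC, a gene of molybdenum cofactor synthesis (11966 to 24634). Longer regions hold a summit by chance more often, and these counts were not tested against rotations. The control library is not given in the sources used here, and a control shared by the lists would add to any overlap between them.

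OpaA summits after chloramphenicol, and less so after rifampicin, were richer in A and T than untreated ones. List length alone does not account for the first: with the top 221 peaks of each list the chloramphenicol mean was 13.3 points above untreated replicate 1, where the untreated replicates differed by 5.67 points. For rifampicin the excess was 4.92 points with all peaks, just above the 4.82 points between the replicates. With the top 221 it was 4.17 points, within their 5.67 points. With a deposited -log10 q of at least 10 the rifampicin mean was 43.9% (23 peaks), against 35.8% and 30.4% in the untreated replicates. There it stood further above replicate 1 than the replicates differed. The reading thus depended on the peaks used, and replicate spread and treatment cannot be told apart with 1 library. Within the chloramphenicol list fold went with A+T content (Spearman rho of 0.544 across peaks, which are not independent replicates). Better recovery of AT-rich DNA was also predicted to leave summits inside untreated regions as AT-rich as the others. That part was not met, as summits outside were richer (45.2% against 39.7%, label rotation test, exact adjusted p = 0.0057). This cannot weigh against better recovery, however. Untreated summits were poorer in A and T (means of 35.5% and 30.7%), so an AT-rich list can have its richer summits outside whether binding or recovery is the cause. A preference of OpaA for AT-rich DNA when translation stops and a better recovery of AT-rich DNA in that library both stay open, and 1 library cannot part them. A move of OpaA to AT-rich sites under these drugs is therefore only a hypothesis.

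The untreated replicates differed in A+T content and along the chromosome, replicate 2 having more origin-proximal summits. Neither share passed the rotation test against 50% (exact adjusted p = 0.298 and 0.262), but that test cannot judge a gradient along the chromosome. The lowest background pileups differed by 1.05 times, which argues against sequencing depth only as far as this background follows depth. The scaling of the deposited values let in no peaks, since 0 peaks had a q-value above the authors' threshold once divided back. Summits of replicate 2 outside replicate 1 regions were origin-proximal more often than those inside (77.7% against 60.0%, a difference of 17.6 points, exact label rotation p = 0.0406), but this follows in large part from the pattern itself, so whether that library held more DNA copies near the origin stays open. Copy number was not measured here, and no biological explanation was tested.

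The p-values, q-values and folds of untreated replicate 2 did not match its own pileups. In this list 100% of the p and q values were 1.8 times, and 100% of the folds 1.2 times, a number with 5 decimals, against at most 1.43% and 16.7% in the other lists. Dividing them by 1.8 and 1.2 brought 100% of 1281 peaks within 1% of the Poisson value, against 0.468% as deposited, and the smallest -log10 q then became 1.30, that of the peak calling threshold, so multiplication of the values after peak calling is a candidate explanation. No biological explanation was tested for this, and why the values would have been multiplied stays open.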
